A study of Gallus gallus with 12 samples.

How the data were processed

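Poly-A RNA from 12 chicken (Gallus gallus) ovarian follicles, 6 from before recruitment and 6 at the F5 stage, was sequenced as paired reads of 100 bp on an Illumina NovaSeq 6000 after TruSeq library preparation, per the labels' protocols. The same 6 birds gave both stages, and samples are named by stage and bird number. The submitters' processing notes name bcl2fastq 2.19, kallisto 0.44.0, DESeq2 1.38.3, DESeq 0.99.484 and the chicken builds GRCg6a and galGal6, with no role or order. kallisto assigns reads to transcripts by pseudoalignment, so reads of near-identical genes are divided by estimation.

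The deposited table holds estimated counts (expected counts) per gene symbol, not normalised, made by the authors with kallisto per the labels, which name the file for it, and the submitters' processing notes. How transcripts were summed to genes is not given in the sources used here. Its values were already whole numbers, and rounding changed none. TPM values named in the labels were not used here. The table held 12470 named genes and 1 row with a blank name, which was left out of library sizes and tests and took 9.02% ± 0.515 of all counts in the Pre-recruitment libraries and 6.6% ± 0.215 in the F5 libraries (SD, n = 6). Gene symbols were used as the table gives them. Of these, 11845 matched a symbol, and 11984 a symbol or synonym, in a RefSeq gene table of another build (GRCg7b), which was used for names only, so no coordinates are given.

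Named genes received between 20628640 and 40887647 counts per library, 26054366 on average before recruitment and 32123891 in F5 follicles, so counting error is small for well-expressed genes and large for genes with a few counts. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes passing filterByExpr by stage (minimum count 10) were kept, 11195 in all, and libraries were scaled by TMM. The factors averaged 1.09 ± 0.0485 before recruitment and 0.923 ± 0.0404 in F5 follicles (SD, n = 6; exact permutation p = 0.00216), so results by library totals alone are given where they differ. Dispersions and quasi-likelihood fits used the robust option, with stage as the only term, and the test was two-sided with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.168. CPM values are TMM-scaled, log2 CPM values use a prior count of 2, and the standard error of a log2 change is its size divided by the square root of its F statistic. Fold changes are those of the fit. Exact permutation tests between stages on library measures used all 924 assignments of the libraries.

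Gene lists were fixed before the data were examined, 42 lists of pathways, complexes, cell types and technical responses with 1258 genes, of which 1035 were in the table and 979 were tested. The other list genes were not analysed here. Lists with 5 or more tested members were compared with all other genes by limma's camera on log2 CPM with a preset correlation of 0.01 and, as an alternative, an estimated correlation. Members were also adjusted over the list alone. Genes are named by a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls among genes past the threshold, with a mean log2 CPM of at least 2, a gene symbol and the same sign in 6 of 6 birds. It adds a fixed panel (MYC, MYCN, MAX, FSHR, LHCGR, STAR, CYP11A1, HSD3B1, CYP17A1, CYP19A1, AMH, INHA, INHBA, FST, BMPR1B, VLDLR, OCLN, CDH2, WT1, FOXL2, PGR, ESR1, VIPR1) and, from each list, up to 4 tested members with the smallest adjusted p. A few genes that the rule takes are not reported here. Genes outside the rule are said to have been named after their values were seen.

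Libraries of 1 stage were compared before use. The smallest chi-square per degree of freedom of a pair was 23.5, so none was a repeat of another, and correlations of log2 CPM were 0.973 to 0.99 within and 0.891 to 0.958 between stages. Both stages come from the same animals by the bird numbers in the labels, and deviations from the stage means correlated across genes at 0.13 to 0.39 for the 2 follicles of 1 bird, against -0.3 to 0.3 for follicles of different birds. Genes are not independent replicates in these correlations. In each stage 5 of 6 follicles correlated best with their own bird's other follicle. The fit with the bird as a block is an alternative, shown beside a result where it changes the call.

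The code was tested on simulated data, counts drawn with the real means and library sizes and known changes. For the F5 against Pre-recruitment comparison over 11160 simulated genes, it recovered 68.7% of genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold. False calls made up 4.92% of calls. Only 67, 67 and 65 simulated genes were changed by these folds, whereas 65.5% of genes were called in the real data. No pairing of birds was simulated. These rates therefore describe the code in that setting and do not measure the sensitivity of the real tests. A simulated list of 30 genes shifted 1.5-fold gave a camera p of 3.03e-76 and an unshifted one 0.266 over 11195 genes. These simulated lists had no correlation between genes.

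Alternatives fixed at the same time as the lists were the bird block, RLE and upper-quartile factors, library totals alone, no filter, a filter of 1 CPM in 6 libraries, DESeq2 1.42.0, the 10 most abundant genes left out, each bird left out, each library left out, the estimated correlation and, for the pairing check, the 1000 most variable genes. Leaving out mitochondrial transcripts, and leaving out 319 genes whose deviations within stages correlated above 0.7 with the oocyte markers, were chosen after seeing the data. Counts of genes and lists were also compared over 100 of the 462 splits of the 12 libraries into 6 and 6, among them the 32 that part the follicles of every bird.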

Results

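Messenger RNA was measured by sequencing in ovarian follicle tissue from 6 laying hens aged 12 months. Each hen gave 1 follicle from before recruitment and 1 follicle called F5, a member of the graded series of yolk-filled follicles that leads to ovulation. Recruitment is the step at which a small follicle enters that series. The 12 libraries therefore formed 2 stages of 6, and every stage held the same 6 birds. Counts assigned to named genes ranged from 20628640 to 29082988 per library before recruitment and from 28044247 to 40887647 in F5 follicles. F5 libraries were the deeper ones in 6 of 6 birds, with an exact two-sided permutation p of 0.0108 between stages (0.0162 after Benjamini-Hochberg adjustment over 6 library measures). Exact sign changes within birds gave p = 0.0312. Mitochondrial transcripts took 10.2% ± 1.01 of named counts before recruitment and 9.41% ± 0.398 in F5 follicles (SD, n = 6; exact permutation p = 0.128). The 6 follicles of a stage came from separate animals, but every bird gave both stages. The main fit for genes treated the 12 libraries as independent, and the bird block is its paired alternative.

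The study names MYC as an upstream regulator in pre-ovulatory follicles, and the comparison its design carries is F5 against Pre-recruitment. The transcriptome differed widely between the stages. In F5 follicles, 22 of 23 tested smooth muscle markers and 28 of 33 genes of fibrillar collagens and their processing were higher, and 18 of 19 oocyte and germ cell markers were lower. No gene list passed with an estimated correlation (lowest adjusted p = 0.806). Of 11195 genes tested with edgeR's quasi-likelihood test, 7333 (65.5%) changed at a Benjamini-Hochberg adjusted p under 0.05, 3681 of them higher and 3652 lower in F5 follicles. At least 2-fold changes were found in 1624 genes and lay mostly on the lower side, with 525 higher and 1099 lower (32.3% higher). At 4-fold or more, 56 genes were higher and 337 lower. Scaling by library totals alone shifted the median log2 change of all genes from 0.02 to -0.22 and made the split of 2-fold changes 282 higher against 1548 lower (15.4% higher). The split of all changed genes was then 2071 higher against 5200 lower (28.5% higher, from 50.2%). Directions given here are therefore relative to the typical gene.

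**Figure D1:**
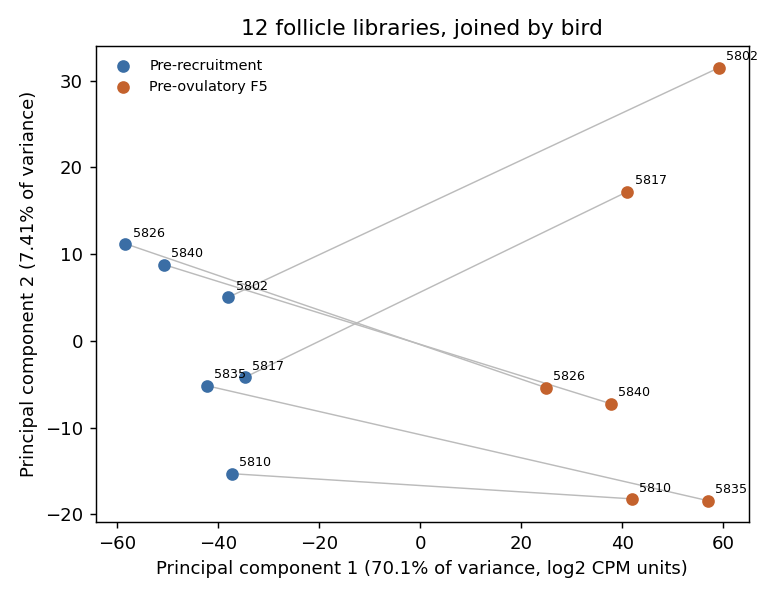
Scores of the 12 libraries on the first 2 principal components of log2 CPM (horizontal axis 70.1% and vertical axis 7.41% of the variance), with 1 point per library, colours for stage, bird numbers beside the points and grey lines joining the 2 follicles of a bird. The Pre-recruitment libraries lie between -58.4 and -34.8 on the horizontal axis and the F5 libraries between 24.8 and 59.2.

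The 8 largest rises among well-expressed genes that moved the same way in 6 of 6 birds ran from 9.43-fold to 42-fold. ACTC1, the cardiac alpha-actin, rose from 2.06 ± 1.2 to 86.4 ± 63.6 CPM (SD, n = 6), a log2 change of 5.39 (SE 0.64, edgeR adjusted p = 8.66e-06). GJD2, which encodes a gap junction connexin, rose 31.7-fold from 0.307 to 9.88 CPM. The collagenases MMP1 and MMP13 rose 11.2-fold and 9.84-fold, and PCOLCE2, an enhancer of procollagen processing, rose 9.43-fold. SFRP4, a secreted WNT antagonist, rose 10.3-fold from 93.4 ± 33.6 to 961 ± 258 CPM (SD, n = 6). ANGPTL5, an angiopoietin-like protein, rose 10.5-fold and SRL, a calcium-binding protein of the sarcoplasmic reticulum, 9.91-fold. Adjusted p-values of these 8 genes ran from 3.58e-09 to 2.05e-04. ACTC1 reads can be shared with other actin genes, so its level is uncertain. Smooth muscle markers rose in the same libraries, by a median of 2.28-fold.

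The 8 largest falls by the same rule ran from 28.9-fold to 47-fold. SLC30A2, a zinc transporter, fell 47-fold, from 10 ± 2.85 to 0.199 ± 0.187 CPM (SD, n = 6). CA9, a carbonic anhydrase, fell 45.6-fold and RGS16, a regulator of G-protein signalling, 45-fold from 39.4 ± 12 to 0.867 ± 0.189 CPM (SD, n = 6). ATP8A2, a phospholipid flippase, fell 30.5-fold, C6orf132 30.4-fold and the glycosyltransferase B3GNT7 29.9-fold. WNT6 fell 28.9-fold from 69.7 ± 14.9 to 2.43 ± 1.43 CPM (SD, n = 6). SPP1, which encodes osteopontin, fell 29.1-fold but from a variable level of 103 ± 113 CPM. With the bird as a block its log2 change was -4.09 in place of -4.86, which is smaller than those of MYCL (-4.20) and AMH (-4.59) in that fit, so its place among the 8 depends on the fit. Without the F5 library of 5826 the log2 change of C6orf132 went from -4.93 to -5.59, and that of SLC30A2 went from -5.55 to -6.15 without bird 5835 and to -6.16 without its F5 library. Each of these 8 genes was lower in 6 of 6 birds, with edgeR adjusted p-values from 2.00e-09 (RGS16) to 9.33e-04 (SPP1). Oocyte and germ cell markers fell in the same libraries, by a median of 4.69-fold. Among libraries of 1 stage, ATP8A2, C6orf132 and WNT6 followed those markers, with r from 0.9 to 0.99 (adjusted permutation p from 7.80e-04 to 0.0017) and rho from 0.85 to 0.99 (adjusted permutation p from 0.0013 to 0.0042). CA9 (r = 0.78, adjusted permutation p = 0.051), SLC30A2 (0.16, 0.75), RGS16 (0.11, 0.75) and SPP1 (-0.21, 0.43) did not pass by r or rho, and B3GNT7 passed by r alone.

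MYC itself, the transcription factor named by the study, was modestly higher in F5 follicles. It rose from 59.5 ± 7.26 to 83.2 ± 12.4 CPM (SD, n = 6), 1.4-fold, in 6 of 6 birds (log2 change 0.48, SE 0.10, edgeR adjusted p = 8.53e-04). Its dimerisation partner MAX fell 1.46-fold, from 30.1 ± 2.3 to 20.7 ± 1.95 CPM. The paralog MYCL changed far more than MYC and in the other direction, from 110 ± 13.6 to 6.1 ± 1.84 CPM, an 18-fold fall (log2 change -4.17, SE 0.17, adjusted p = 1.96e-09). Whether MYCL follows the oocyte markers, which fell in the same libraries, was left undecided (r = 0.67 among libraries of 1 stage, adjusted permutation p = 0.11). MYCN stood at 3.2 and 3.78 CPM (adjusted p = 0.0987). Among the antagonists that compete for MAX, MXD1 rose 1.83-fold and MNT fell 1.55-fold. Of 11 tested MYC network factors, 4 rose, 4 fell and 3 did not pass the test. Their median log2 change was -0.09 (camera adjusted p = 0.821).

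A general list of MYC target genes, which was not chosen on these samples, went both ways. Of 49 tested targets, 21 rose, 13 fell and 15 did not pass the test. MYC itself is on the list and is among the 21 that rose. Adjusted over the list alone, 21 rose and 14 fell. MYC was named by the study from these same follicles, so the rise of MYC and the list's direction are not independent of that choice. SRM, a spermidine synthase, rose 1.78-fold from 47.3 ± 3.7 to 84.2 ± 7.99 CPM, and the arginine methyltransferase PRMT3 rose 1.64-fold. UNG, a uracil-DNA glycosylase, fell 2.3-fold from 63.3 ± 6.78 to 27.6 ± 2.2 CPM (SD, n = 6), and PPRC1, a transcriptional coactivator, fell 2.34-fold. Each of these 4 targets moved the same way in 6 of 6 birds, with edgeR adjusted p-values from 3.80e-08 to 1.61e-06. The median log2 change of the targets was 0.02, and camera gave an adjusted p of 0.678 over 42 lists (adjusted p = 0.975 with an estimated correlation). Ribosome biogenesis genes, a group that MYC is known to drive, were likewise mixed, with 17 higher and 12 lower of 39 tested (median 0.08, camera adjusted p = 0.692). UBTF, a factor for ribosomal RNA transcription, rose 1.47-fold, and UTP4, a ribosome assembly factor, fell 1.77-fold. Scaling by library totals turned the median of the targets to -0.21 and that of ribosome biogenesis to -0.15. Leaving out bird 5835, or its Pre-recruitment library alone, turned the median of the targets to -0.015 and -0.014.

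**Figure D2:**
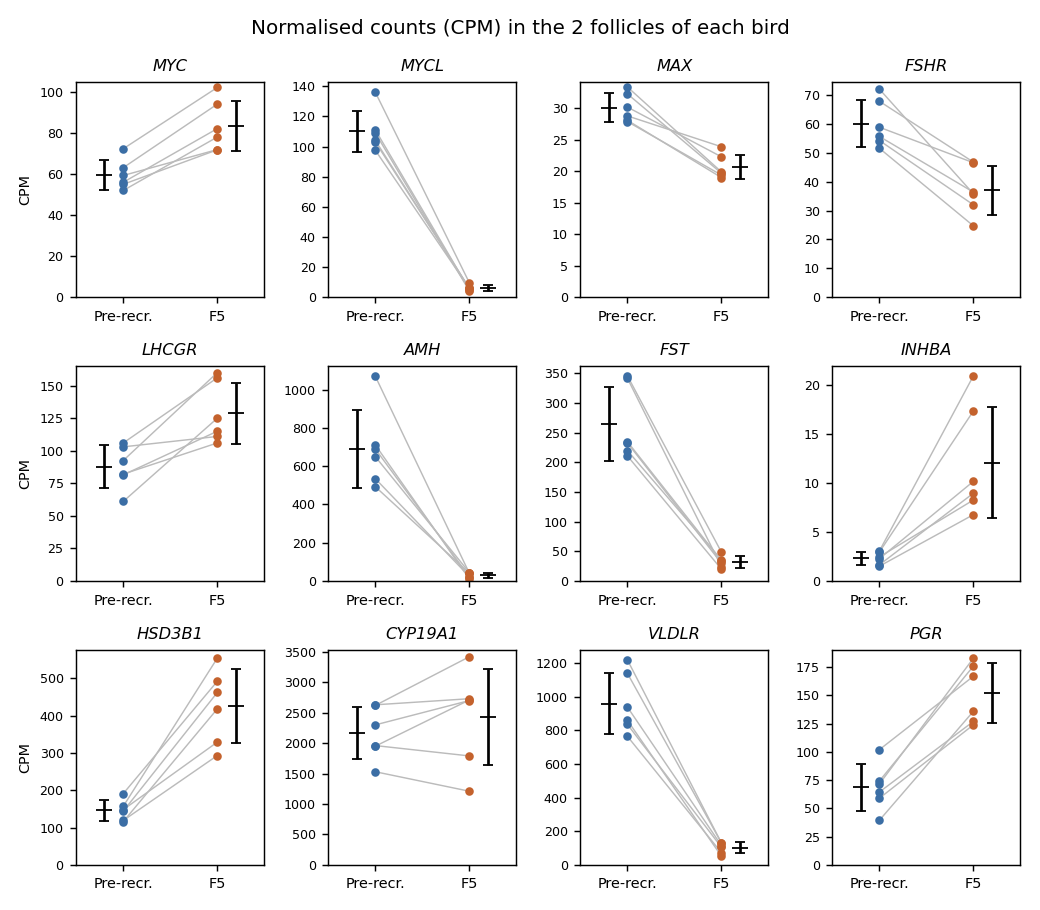
Normalised counts (CPM, vertical axes from 0) of 12 genes in the Pre-recruitment and F5 follicles, with 1 point per library, grey lines joining the follicles of 1 bird, and black bars for the mean ± SD of 6 libraries. MYC lies higher in F5 follicles in 6 of 6 birds (59.5 to 83.2 CPM) and MYCL lower in 6 of 6 (110 to 6.1 CPM), while CYP19A1 goes both ways between birds.

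Cytoplasmic ribosomal proteins were higher as a group, with 44 risers, no fallers and 20 below the threshold among 64 tested (median log2 change 0.43, camera adjusted p = 3.41e-06). With an estimated correlation the adjusted p = 0.895, so that call rests on the preset correlation. The mean score of the list was higher in F5 follicles in 5 of 6 birds and lower in bird 5817 (0.09 before recruitment and -0.04 in F5, log2 units around the mean of all libraries). RPS24 rose 2.1-fold from 656 ± 69.2 to 1380 ± 169 CPM (edgeR adjusted p = 5.70e-07, 6 of 6 birds). Whether reads of ribosomal protein genes were shared with near-identical sequences was not measured, so their levels are uncertain to that extent. Endoplasmic reticulum chaperones and unfolded protein response genes also rose, 22 of 27 tested, with 2 fallers (3 adjusted over the list alone), a median of 0.70 and a camera adjusted p of 2.93e-05 (adjusted p = 0.806 with an estimated correlation). ATF4, a transcription factor of the stress response, rose 1.95-fold from 523 ± 45.9 to 1020 ± 100 CPM, and its target ASNS, the asparagine synthetase, 2.76-fold. P4HB, a protein disulfide isomerase that is also a subunit of the collagen prolyl hydroxylase, rose 1.86-fold to 1590 ± 117 CPM, and CRELD2, an endoplasmic reticulum stress-inducible protein, 2.3-fold. These 4 genes were higher in 6 of 6 birds. In the same libraries smooth muscle markers rose by a median of 2.28-fold and oocyte markers fell by a median of 4.69-fold.

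More proliferation genes fell than rose in F5 follicles, beside the fall of oocyte markers in the same libraries. In the DNA replication list, 20 of 38 tested members fell and 5 rose (median log2 change -0.24, camera adjusted p = 0.0312; adjusted p = 0.895 with an estimated correlation). CDT1, a licensing factor for replication origins, fell 3.22-fold from 73.5 ± 14.6 to 22.8 ± 2.11 CPM (SD, n = 6), RFC4, a clamp loader subunit, 2.07-fold, and MCM2, a subunit of the replicative helicase, 1.98-fold. The list missed the threshold without bird 5826 (camera adjusted p = 0.056) or 5840 (0.0566), without the Pre-recruitment library of 5840 (0.0631) and without the F5 library of 5826 (0.0537). Of 44 cell cycle and mitosis genes, 17 fell and 5 rose (16 and 4 adjusted over the list alone), with a median of -0.19 and a camera adjusted p of 0.134. CCNB1, the mitotic cyclin B1, fell 5.32-fold from 736 ± 136 to 138 ± 19.1 CPM (log2 change -2.41, SE 0.13, edgeR adjusted p = 9.04e-09). Whether CCNB1 follows the oocyte markers among libraries of 1 stage was left undecided (r = 0.48, adjusted permutation p = 0.13, and rho = 0.56, adjusted permutation p = 0.097). The mitotic kinase AURKA fell 2.59-fold and the phosphatase CDC25A 2.49-fold. These 6 genes were lower in 6 of 6 birds.

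Granulosa cells line the follicle around the oocyte, and their markers split between the stages. Of 22 tested, 13 fell, 4 rose and 5 did not pass the test (median log2 change -0.94, camera adjusted p = 0.0481; adjusted p = 0.806 with an estimated correlation). AMH, a granulosa hormone of small follicles, fell 22.8-fold from 691 ± 203 to 30.4 ± 13.3 CPM (SD, n = 6; log2 change -4.51, SE 0.33, edgeR adjusted p = 1.24e-07). FST, which binds activins, fell 8.22-fold from 264 ± 62 to 32.2 ± 10 CPM, and OCLN, a tight junction protein, 4.06-fold. Oocyte markers fell in the same libraries, by a median of 4.69-fold, and OCLN followed them among libraries of 1 stage (r = 0.69, adjusted permutation p = 0.019, and rho = 0.66, adjusted permutation p = 0.043). AMH (r = 0.43, adjusted permutation p = 0.43) and FST (-0.26, 0.62) did not pass that test by r or rho. The transcription factors FOXL2, GATA4 and WT1 fell 2.49-fold, 2.38-fold and 2-fold, and the adhesion molecule CDH2 1.84-fold. INHBA, the inhibin and activin beta-A subunit, rose 5.2-fold from 2.33 ± 0.648 to 12.1 ± 5.73 CPM. The other risers, named after their values were seen, were NR5A2, a nuclear receptor (3.56-fold), GJA1, a gap junction protein (1.52-fold, higher in 5 of 6 birds), and KITLG, the KIT ligand (1.32-fold). KITLG missed the threshold under library totals (adjusted p = 0.244). INHA, the inhibin alpha subunit, went from 36 ± 40.8 to 90.2 ± 62.1 CPM (adjusted p = 0.123) and passed without bird 5802 (log2 change 2.42, adjusted p = 0.00115) or its Pre-recruitment library (2.16, 0.0109). The list's call sat at its threshold, ending under library totals (camera adjusted p = 0.228), with no low-count filter (0.0693), with the 1 CPM filter (0.0501) and with DESeq2 (0.0568). It also ended without bird 5802 (0.0671) or 5817 (0.0696), without the Pre-recruitment library of 5802 (0.0661), 5810 (0.0557) or 5840 (0.0545), and without the F5 library of 5802 (0.0623) or 5817 (0.0648).

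Receptors of the gonadotropins moved in opposite directions. FSHR fell 1.62-fold from 60.1 ± 8.12 to 37.1 ± 8.54 CPM (SD, n = 6; edgeR adjusted p = 6.48e-04), lower in 6 of 6 birds. LHCGR, the luteinizing hormone receptor, rose 1.47-fold from 87.6 ± 16.5 to 129 ± 23.4 CPM (adjusted p = 0.0028), higher in 6 of 6 birds, though under library totals its adjusted p was 0.0674. VIPR1, a receptor for vasoactive intestinal peptide, stood at 2.05 ± 0.673 and 1.39 ± 0.363 CPM (adjusted p = 0.0558, or 0.0242 with the bird as a block). VIPR1 also passed under library totals (0.0141), with DESeq2 (0.0489) and without the genes that follow the oocyte markers (0.0459), and without the Pre-recruitment library of 5810 (0.0258) or 5826 (0.0341) or the F5 library of 5817 (0.0225). In the list of gonadotropin receptors and cAMP signalling, 16 of 31 tested rose and 7 fell (16 and 9 adjusted over the list alone; median 0.33, camera adjusted p = 0.292). PRKAR2B, a regulatory subunit of protein kinase A, rose 2.88-fold and the phosphodiesterase PDE10A 2.3-fold, while the adenylate cyclase ADCY9 fell 1.4-fold, each in 6 of 6 birds. PGR, the progesterone receptor, rose 2.22-fold from 68.6 ± 20.6 to 152 ± 26 CPM, and the estrogen receptor ESR1 measured 12.4 ± 2.08 and 14.8 ± 3.98 CPM (adjusted p = 0.203).

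Steroid synthesis genes showed 1 clear rise in the progesterone pathway and several smaller changes. HSD3B1, which converts pregnenolone to progesterone, rose 2.91-fold from 146 ± 27.4 to 424 ± 99.2 CPM (SD, n = 6; log2 change 1.54, SE 0.16, edgeR adjusted p = 2.01e-06) in 6 of 6 birds. STAR, the mitochondrial cholesterol carrier, measured 234 ± 52.7 and 302 ± 66.3 CPM (adjusted p = 0.0613, or 0.0391 with the bird as a block), higher in 5 of 6 birds. STAR passed with DESeq2 (0.0483), without bird 5802 (0.0179), without the Pre-recruitment library of 5802 (0.0383) or 5810 (0.0333), and without the F5 library of 5802 (0.0332) or 5817 (0.0323). CYP11A1, the side-chain cleavage enzyme, measured 604 ± 156 and 674 ± 110 CPM (adjusted p = 0.43). CYP19A1, the aromatase, measured 2170 ± 432 and 2430 ± 790 CPM (adjusted p = 0.522), and both log2 changes turned negative under library totals (-0.07 and -0.06). CYP17A1, which makes androgen precursors in theca cells, fell 1.26-fold from 1090 ± 240 to 863 ± 107 CPM (adjusted p = 0.037), lower in 5 of 6 birds. That fall missed the threshold without bird 5802 (0.14), 5810 (0.0562) or 5817 (0.0754), and without the F5 library of 5802 (0.0809), 5817 (0.0727) or 5826 (0.0655). HSD17B1, an estradiol-forming enzyme, fell 2.22-fold and FDXR, the ferredoxin reductase, 1.83-fold. The steroid list as a whole had 6 risers and 5 fallers of 18 (median 0.11, camera adjusted p = 0.881). In cholesterol synthesis, 10 of 21 rose and 6 fell (median 0.28, camera adjusted p = 0.377), with the early enzyme HMGCS1 up 1.82-fold and MVK and FDFT1 down 2.14-fold and 2.36-fold.

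Growth factor pathways contained members with large changes but no list call. In TGF-beta superfamily signalling, 16 of 39 tested rose and 11 fell (17 and 11 adjusted over the list alone). Its median was 0.14, its mean -0.18 and its camera adjusted p 0.48 in the upward direction. BMPR1B, a receptor for bone morphogenetic proteins, fell 2.36-fold from 35 ± 2.21 to 14.9 ± 2.74 CPM, and the ligand BMP5 rose 2.41-fold (edgeR adjusted p = 5.09e-07 and 1.03e-06). In WNT signalling 10 of 35 rose and 12 fell (median -0.13, camera adjusted p = 0.746), with the antagonists WIF1 and SFRP2 down 13.8-fold and 3.86-fold beside the rise of SFRP4 and the fall of WNT6. Among EGF and FGF family genes 10 of 27 rose and 10 fell (median -0.05, camera adjusted p = 0.952). BTC, an EGF receptor ligand, fell 23.6-fold from 38.2 ± 9.61 to 1.61 ± 0.705 CPM and FGF16 4.27-fold. FGF16 passed the test of following the oocyte markers among libraries of 1 stage (r = 0.43, adjusted permutation p = 0.044, and rho = 0.65, adjusted permutation p = 0.0042). Its r was no higher than that of AMH (0.43), which did not pass, so by r it followed them only weakly. BTC (r = 0.7, adjusted permutation p = 0.052) and WIF1 (-0.36, 0.62) did not pass that test by r or rho. Of 13 hedgehog genes 5 fell and none rose (median -0.04, camera adjusted p = 0.48), including the ligand IHH (3.57-fold). Of 16 Notch genes 6 fell and 2 rose (median -0.04, camera adjusted p = 0.48), with the effector HEY2 down 3.62-fold and the ligand JAG1 up 1.86-fold.

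Oocyte and germ cell markers were lower in the F5 libraries. Of 19 tested, 18 fell, none rose and 1 did not pass, with a median log2 change of -2.23, a 4.69-fold fall (camera adjusted p = 5.00e-05; adjusted p = 0.895 with an estimated correlation). BRDT, a germ cell bromodomain protein, fell 6.92-fold from 102 ± 22.5 to 14.7 ± 3.42 CPM (SD, n = 6; log2 change -2.79, SE 0.18, edgeR adjusted p = 2.81e-08), PIWIL1, which binds germline small RNAs, 7.5-fold, and TDRD1, its Tudor-domain partner protein, 4.03-fold. These 3 genes were lower in 6 of 6 birds. DDX4, named after its values were seen, was the marker that did not pass (0.551 ± 0.186 and 0.247 ± 0.244 CPM, adjusted p = 0.0846). Of 6 vitelline membrane and zona pellucida genes, 3 fell (median -1.19, camera adjusted p = 0.478). ZP2 fell 16.6-fold from 196 ± 52.9 to 11.9 ± 10.6 CPM and ZPAX 4.11-fold (adjusted p = 0.0164, and 0.0556 without bird 5840). ZPAX followed the oocyte markers among libraries of 1 stage (r = 0.98, adjusted permutation p = 8.70e-04, and rho = 0.98, adjusted permutation p = 0.0022). ZP1, a granulosa list member too, measured 194 ± 85.1 and 128 ± 53.7 CPM (adjusted p = 0.084) and was lower in 6 of 6 birds, with an adjusted p of 2.61e-05 when the bird was a block. ZP1 also passed under library totals (0.0132), without bird 5810 (0.0186), without the Pre-recruitment library of 5840 (0.0338) and without the F5 library of 5810 (0.0156).

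Genes of lipid uptake moved with a wide range beside these markers. VLDLR, the hen oocyte's receptor for yolk precursors, fell 9.51-fold from 960 ± 182 to 101 ± 32.3 CPM (SD, n = 6; log2 change -3.25, SE 0.22, edgeR adjusted p = 5.62e-08). NPC1, which exports cholesterol from lysosomes, fell 6.8-fold from 1020 ± 122 to 149 ± 30.8 CPM. DGAT2, a triglyceride-forming enzyme, fell 16.2-fold, and LPL, which hydrolyses lipoprotein triglyceride, 2.31-fold, all 4 genes in 6 of 6 birds. In the list of lipoprotein uptake and lipid handling, 14 of 27 fell and 8 rose (median -0.28, camera adjusted p = 0.481). Of 17 tight and gap junction genes 7 fell and 5 rose, with a median of 0.01, a mean of -0.06 and a camera adjusted p of 0.647 in the downward direction. CLDN1, a tight junction claudin, fell 5.4-fold. Epithelial markers had 10 fallers and 5 risers of 21 (median -0.27, camera adjusted p = 0.45), with the adhesion molecule EPCAM down 19.5-fold from 140 ± 36.2 to 7.2 ± 4.92 CPM and the desmosomal protein DSP 2.47-fold. EPCAM followed the oocyte markers among libraries of 1 stage (r = 0.87, adjusted permutation p = 0.0066, and rho = 0.93, adjusted permutation p = 0.0042). VLDLR (r = 0.52, adjusted permutation p = 0.29), NPC1 (0.72, 0.087), DGAT2 (0.78, 0.052) and CLDN1 (0.38, 0.56) did not pass that test by r or rho.

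Smooth muscle and collagen genes were higher in the F5 libraries. Of 23 smooth muscle markers, 22 rose and 1 did not pass (median log2 change 1.19, 2.28-fold; camera adjusted p = 3.41e-06; adjusted p = 0.832 with an estimated correlation). TPM1, a tropomyosin, rose 4.66-fold from 1220 ± 285 to 5660 ± 1390 CPM (SD, n = 6; edgeR adjusted p = 4.15e-07). CALD1, which encodes caldesmon, rose 3-fold and VCL, which encodes vinculin, 2.17-fold. Of 33 fibrillar collagens and collagen-processing genes, 28 rose and 1 fell (median 0.89, 1.86-fold; camera adjusted p = 3.46e-07; adjusted p = 0.806 with an estimated correlation). FN1, which encodes fibronectin, rose 3.11-fold from 1500 ± 269 to 4690 ± 333 CPM, LOX, which crosslinks collagen, 4.35-fold, and PLOD2, a collagen lysyl hydroxylase, 2.24-fold. Matrix proteases and inhibitors had 15 risers and 3 fallers of 24 (median 0.51, camera adjusted p = 0.00606; adjusted p = 0.806 with an estimated correlation). MMP10, a stromelysin, rose 5.16-fold from 970 ± 250 to 5000 ± 990 CPM, and ADAM12, a membrane-bound metalloprotease, 4.14-fold. Each gene named here was higher in 6 of 6 birds. Of 16 basement membrane genes 8 rose and 5 fell (median 0.25, camera adjusted p = 0.48), with COL4A1 and COL4A2 up 2.45-fold and 2.41-fold and agrin (AGRN) down 1.43-fold.

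**Figure D3:**
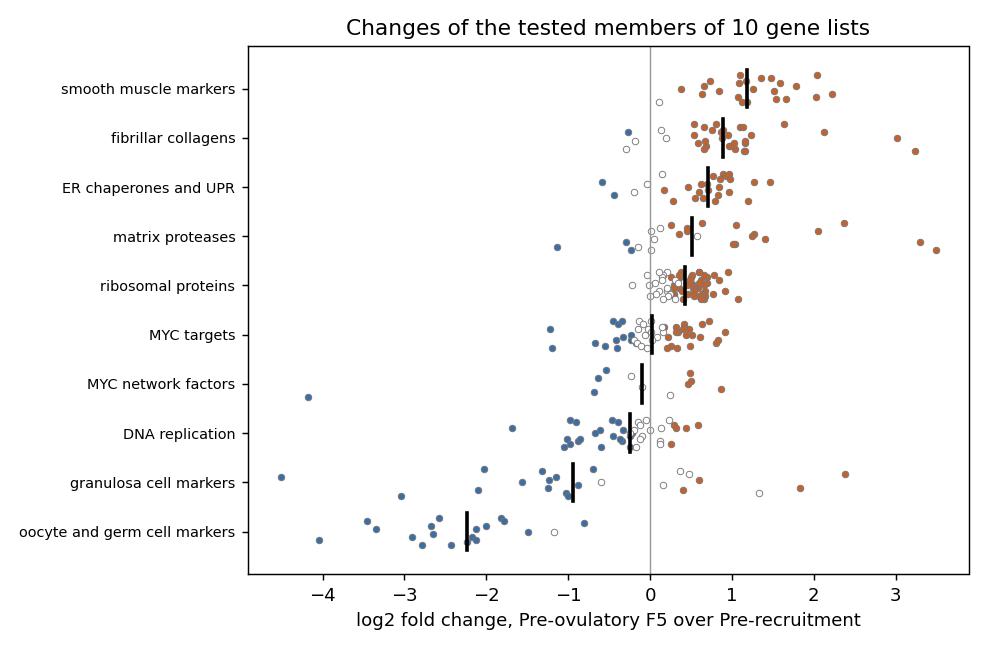
Log2 fold changes (horizontal axis, F5 over Pre-recruitment) of the tested members of 10 gene lists, with 1 point per gene, filled where the adjusted p was under 0.05 and hollow where not, and a black bar at each list's median. Smooth muscle markers have a median of 1.19 and oocyte markers of -2.23, while MYC targets spread to both sides of a median of 0.02.

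Markers of other cell types present in follicle wall or blood did not pass the test as groups. Theca and stroma markers had 13 risers and 5 fallers of 23 (median 0.43, camera adjusted p = 0.0715), including NR2F2, a stromal nuclear receptor (1.82-fold), the proteoglycan DCN (1.97-fold) and THY1 (2.47-fold). Endothelial markers had 11 risers and 4 fallers of 24 (median 0.18, camera adjusted p = 0.434), with PECAM1 up 1.67-fold and EGFL7 down 1.8-fold. Angiogenic factors had 13 risers and 3 fallers of 23 (median 0.33, camera adjusted p = 0.134), and THBS1, a thrombospondin that inhibits angiogenesis, rose 5.49-fold from 274 ± 74.4 to 1510 ± 481 CPM (edgeR adjusted p = 1.01e-06, 6 of 6 birds). Nerve and glial markers had 10 fallers and 1 riser of 20 (median -0.52, camera adjusted p = 0.0573), with the neurotrophin receptor NGFR down 9.37-fold, the neurofilament NEFL 8.32-fold and UCHL1, a neuronal ubiquitin hydrolase, 2.32-fold. NEFL followed the oocyte markers among libraries of 1 stage (r = 0.84, adjusted permutation p = 0.0067, and rho = 0.89, adjusted permutation p = 0.0042). NGFR did not pass that test by r (0.2, adjusted permutation p = 0.75) or rho. The theca list passed without bird 5835 (0.0483) or its Pre-recruitment library (0.0491), under library totals (0.00858) and with DESeq2 (0.0481). The nerve list passed without bird 5802 (0.029) or its F5 library (0.0257) and without the Pre-recruitment library of 5817 (0.0461). These passes used the preset correlation. With an estimated correlation and all libraries, the camera adjusted p was 0.895 for the theca list and 0.806 for the nerve list. Pericyte markers had 2 risers and 2 fallers of 5 (median 0.06, camera adjusted p = 0.952), with RGS5 down 1.6-fold. Thrombocyte markers had 5 risers and 2 fallers of 11 (median 0.75, camera adjusted p = 0.445), among them the integrin ITGB3 (2.86-fold). Macrophage markers had 4 risers and 3 fallers of 28 (1 and 1 adjusted over the list alone; median 0.24, camera adjusted p = 0.559). Lymphocyte markers had 3 and 2 of 25 (1 riser and no fallers adjusted over the list alone), with a median of -0.02, a mean of -0.05 and an upward camera adjusted p of 0.952. Heterophil markers had 1 and 1 of 8 (median 0.43, camera adjusted p = 0.952), the riser being the gelatinase MMP9, up 2.64-fold. CXCR1, a chemokine receptor, measured 0.907 ± 0.241 and 0.603 ± 0.188 CPM (edgeR adjusted p = 0.0602, or 0.0386 with the bird as a block) and was lower in 6 of 6 birds. It also passed under library totals (0.0142), without bird 5835 (0.0499) or its F5 library (0.0399), without the Pre-recruitment library of 5817 (0.029) and without the F5 library of 5826 (0.0351). Erythroid markers had 3 and 1 of 12 (2 and 1 adjusted over the list alone; median -0.05, camera adjusted p = 0.952).

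Apart from the endoplasmic reticulum list, stress, immune and energy lists gave no list call either. Immediate early genes, which respond to handling of tissue, had 11 risers and 2 fallers of 21 (median 0.44, camera adjusted p = 0.0977), with CYR61 up 4.26-fold and KLF6 2.19-fold. Heat shock proteins had 8 risers and 4 fallers of 20 (median 0.30, camera adjusted p = 0.45), HSPB1 up 2.32-fold and CRYAB down 2.34-fold. Apoptosis regulators had 15 risers and 4 fallers of 25 (median 0.31, camera adjusted p = 0.0584), with the death receptor FAS up 2.33-fold and the caspase CASP6 3.11-fold. Oxidative phosphorylation had 25 risers and 8 fallers of 54 (median 0.15, camera adjusted p = 0.0994), NDUFA4 up 2.62-fold. The immediate early list passed without bird 5840 (0.0469) or its F5 library (0.035) and under library totals (0.0131). The apoptosis list passed without bird 5817 (0.0414) or 5840 (0.0492), without the Pre-recruitment library of 5817 (0.0461), under library totals (0.0414), with DESeq2 (0.0467) and without the genes that follow the oocyte markers (0.0376), and oxidative phosphorylation without bird 5817 (0.0129) or its F5 library (0.0227). All of these passes used the preset correlation. With an estimated correlation and all libraries, the camera adjusted p was 0.895 for immediate early genes, 0.806 for apoptosis and 0.975 for oxidative phosphorylation. Glycolysis had 6 and 7 of 20 (median -0.04, camera adjusted p = 0.911), with the kinase HK2 up 1.89-fold. Interferon response had 5 and 7 of 19 (median -0.13, camera adjusted p = 0.952). Complement and acute phase had 1 and 3 of 15, with a median of 0.18, a mean of -0.03 and an upward camera adjusted p of 0.952; C5 fell 3.7-fold.

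Over all 42 lists, camera with its preset correlation called 8, of which 5 were higher and 3 lower in F5 follicles, and 15 had an unadjusted p under 0.05. With an estimated correlation none passed (lowest adjusted p = 0.806) and 2 had an unadjusted p under 0.05, and 76 of 100 splits of the 12 libraries gave 8 or more lists, the real split included. For 34 of the 42 lists the counts of members adjusted over the list alone equalled those over all genes.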

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

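The tests of marker co-variation, of a single fold for the oocyte markers, of granulosa members that rose, and of actin reads were chosen after the results they bear on were seen. The bounds for the scaling alternatives and the splits were set before.

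The row with no gene name, which no comparison uses, held 9.02% ± 0.515 of all counts in Pre-recruitment libraries and 6.6% ± 0.215 in F5 libraries (SD, n = 6), lower in F5 follicles in 6 of 6 birds (exact two-sided permutation p = 0.00216, 0.00433 after adjustment over 6 library measures, and 0.0312 by exact sign changes within birds). What transcripts it holds was not analysed here.

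Oocyte and germ cell markers fell by a median of 4.69-fold in the F5 libraries. None of the scalings and gene exclusions run accounts for the fall, since the median stayed at -2.23 or lower under all of them. They moved the median of all genes only between 0.02 and -0.22, so larger errors of scaling were not tested. A smaller share of oocyte RNA in the sampled tissue may contribute, because the 19 markers rose and fell together among libraries of 1 stage with a mean pairwise correlation of 0.672, above the highest of 10000 expression-matched random lists (0.212), and of 0.654 without the 2 libraries farthest from the median score. Whether it is the only cause stays open, since 84.6% of the spread between the markers' log2 changes, from -0.80 (NPM2) to -4.05 (ZP2), exceeded their standard errors, but unequal folds would exclude it only if each marker came from the oocyte alone, which was not measured. How much oocyte entered each tissue sample, and transcription per oocyte at the 2 stages, were not tested and stay open.

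Granulosa markers went both ways, 13 lower and 4 higher. None of the scalings and gene exclusions run removed the split. Members passed the threshold in both directions under all of them, at least 3 in the rarer direction, among them INHBA. These settings moved the median of all genes only between 0.02 and -0.22, so larger errors of scaling were not tested. A lower share of granulosa RNA as the only cause stays open, because the 3 or more members that rose would exclude it only if they came from granulosa cells alone, which was not measured. Stage itself stays open and was not tested.

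Smooth muscle markers rose by a median of 2.28-fold. Under the scaling least favourable to the rise, library totals, the median was 0.95, so none of the scalings run accounts for the rise. They moved the median of all genes only between 0.02 and -0.22, so larger errors of scaling were not tested. Without the 2 actin genes of the list the median was 1.18, so the other members rose without them. Leaving out 2 of 23 members can hardly move a median, so this says nothing on reads shared among the actin genes themselves. For ACTC1, counts per 100 ACTA2 counts went from 0.0873 ± 0.0362 to 0.85 ± 0.444 (SD, n = 6; exact two-sided permutation p = 0.00216), which a fixed leak of ACTA2 reads forbids. A larger share of smooth muscle RNA in the F5 libraries is consistent with the mean pairwise correlation of 0.604 among markers within stages (0.451 was the highest of 10000 random lists), though it fell to 0.376 without the 2 libraries farthest from the median score. Whether stage or the part of the wall that was sampled sets that share was not tested.

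Other groupings of the libraries do not give the gene counts. Of 100 splits drawn from 462, 1 gave 7333 or more genes, the real one, and the highest other gave 2025. For 2-fold changes 1 gave 1624 or more and the highest other gave 359. Among the 32 splits that part every bird's pair, the real one was again the highest, 30 of the others called no gene, and the exception was the split that exchanges the follicles of bird 5817. For gene lists, 76 of 100 splits gave 8 or more and the highest other gave 18, so chance is not excluded for that count. For the MYC targets, 63 of 100 splits gave a median as far from 0 and the highest other was 0.086, so chance is not excluded there. Among the 32 splits that part every pair, 24 gave as many lists (highest other 15) and 21 gave as large a median of MYC targets (highest other 0.080).

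Single libraries stood apart from the other 5 of their stage in 16 of 292 groups of values tested, where chance gives about 1 in 20 or 14.6. In bird 5826, the Pre-recruitment follicle was the highest for SLC30A2 (15.5 CPM, others up to 10.5), FOXL2 (402, others up to 303), MYCL (136, others up to 111) and MVK (107, others up to 85.3). Its F5 follicle was the highest for MMP1 (10.6 CPM, others up to 7.06) and MYCL (9.58, others up to 5.95) and the lowest for CRELD2 (117, others from 165). In bird 5802, the Pre-recruitment follicle was the highest for INHA (117 CPM, others up to 37.1) and TH (18.9, others up to 4.75), and the F5 follicle for KITLG (32.9, others up to 24), with the fewest genes detected (11836, others from 11943). In bird 5835 the F5 follicle was the highest for SPP1 (8.65 CPM, others up to 3.38) and had no TH count (0 CPM, others up to 0.0376, where 1 count is the difference). In bird 5817 the F5 follicle was the lowest for WIF1 (3.78 CPM, others from 12.9) and the Pre-recruitment follicle the highest for ALB (14.3, others up to 7.51). In bird 5810 the Pre-recruitment follicle was the highest for ZP1 (359 CPM, others up to 185).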

How the results depend on the processing

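Leaving out mitochondrial transcripts and leaving out genes that follow the oocyte markers were chosen after seeing the data, and the other alternatives before. The count of changed genes was 6750 to 7711 over all alternatives (7711 with the bird as a block, 7271 under library totals, 7633 with DESeq2) and that of 2-fold changes 1387 to 1859, the lowest without the 319 genes that follow the oocyte markers. Between 6 and 10 gene lists passed, except that none passed with an estimated correlation (0 against 8). The lowest correlation between follicles of 1 bird was 0.13, and 0.2 over the 1000 most variable genes. The bird block changed the calls of STAR, VIPR1, ZP1 and CXCR1 and no other call of a gene that the naming rule takes or of a list.

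The median of the MYC target list was not past the threshold in any alternative, and it turned to -0.21 under library totals, which shifts all genes, and to -0.00065 without the genes that follow the oocyte markers. Leaving out a bird or library gave -0.015 to 0.088, with the cause not tested. Under library totals the medians of 8 other uncalled lists also turned negative, those of ribosome biogenesis (-0.15), steroid synthesis (-0.12), TGF-beta signalling (-0.093), oxidative phosphorylation (-0.084), junctions (-0.22), complement (-0.048), pericytes (-0.16) and endothelium (-0.046), with CYP11A1 (-0.072) and CYP19A1 (-0.058). With no filter, 3 uncalled medians changed sign, EGF and FGF signalling (0.013), junctions (-0.45) and lymphocytes (0.15), and with DESeq2 the same lists did (0.0051, -0.46 and 0.15), where more low-count members are tested. EGF and FGF signalling was 0.046 without the genes that follow the oocyte markers. Leaving out birds or libraries, medians near 0 changed sign in hedgehog (-0.19 to 0.033), junctions (-0.17 to 0.015), interferon (-0.26 to 0.056), pericyte (-0.017 to 0.16), lymphocyte (-0.18 to 0.071), heterophil (-0.14 to 0.70) and erythroid (-0.45 to 0.096) lists, none of which is called, and the cause was not tested. The simulated tests, with few genes changed and no pairing, missed mostly changes of 1.5-fold, of which they recovered 68.7%. Recovery in the real data was not measured. With 20628640 or more counts per library, depth limits genes with a few counts such as TH and DDX4.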

Other observations

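The test of genes that follow the oocyte or granulosa markers had its bounds set before its result was seen, while the genes shown from it were chosen after seeing their correlations.

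Among the nerve and glial markers, TH, the rate-limiting enzyme of catecholamine synthesis, was close to absent from the F5 libraries. It had 876 counts over the 6 Pre-recruitment libraries, 524 of them in bird 5802, and 5 counts over the 6 F5 libraries, and it was lower in 6 of 6 birds (edgeR adjusted p = 2.32e-05). Among transcripts of plasma proteins that the liver mainly makes, ALB (albumin) rose 8.41-fold from 7.24 ± 3.71 to 61.1 ± 24.3 CPM (SD, n = 6, edgeR adjusted p = 4.01e-06). LCAT, a cholesterol-esterifying enzyme, rose 8.06-fold from 3.1 ± 0.951 to 25.1 ± 5.24 CPM (SD, n = 6, edgeR adjusted p = 4.02e-08). The others chosen here did not rise with them. APOA1 measured 700 ± 247 and 760 ± 133 CPM (edgeR adjusted p = 0.646). FGB, VTG1 and TTR were lower 1.94-fold, 3.16-fold and 7.93-fold from levels of 2.51, 1.58 and 3.52 CPM (edgeR adjusted p = 3.46e-04, 0.00196 and 0.0101). In the complement and acute phase list, 1 of 15 tested genes rose, C1R at 1.46-fold (edgeR adjusted p = 0.017), and 3 fell. TH, ALB, LCAT, APOA1, FGB, VTG1 and TTR were chosen after their values were seen.

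The oocyte marker score varied more among F5 libraries (SD 1.28 log2 units, n = 6) than among Pre-recruitment libraries (SD 0.298, n = 6), and the F5 libraries of birds 5835 and 5802 lay farthest below their stage mean (-1.64 and -1.54). Both spreads come from libraries of 1 stage only and no test of their difference was made.

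A hypothesis was that many of the strongly falling genes follow oocyte RNA. Over 319 genes that fell at least 4-fold and belong to neither marker list (a set chosen by fold, not the equally many left out as following the oocyte markers), the median correlation of within-stage deviations with the oocyte marker score was 0.588, against a 95th percentile of 0.103 for 10000 expression-matched random lists (permutation p = 1.00e-04, the smallest that the 10000 permutations of libraries within stages can give). The median Spearman correlation was 0.559, and the median Pearson correlation without the 2 libraries farthest from the median score was 0.577. Correlations above 0.7 were found in 129 of these genes (40.4%) and in 3% of all tested genes. The same test with the granulosa marker score gave a median of 0.296 (permutation p = 0.128), under the bound of 0.5 set for it, though still above the highest of its random lists (0.185). Its median Spearman correlation was 0.203. Without the 2 libraries farthest from the median of the granulosa score, its median Pearson correlation was 0.141. By stage, medians were 0.791 before recruitment and 0.659 in F5 follicles for the oocyte score, and -0.511 and 0.462 for the granulosa score. Part of the 4-fold falls may therefore reflect oocyte RNA in the sampled tissue and not a change in the follicle wall. The deviations were taken within stages, so they do not show what lowered these genes between stages. A change in the wall or in the oocyte that differs among follicles of 1 stage would look alike.

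Single genes were then tested against the oocyte score, while differences between genes were not tested. Of 26 that fell at least 4-fold, tested with 100000 permutations within stages, 9 passed the adjusted threshold by r and 8 by rho. Past both were ATP8A2, C6orf132, WNT6, ZPAX, EPCAM, NEFL, OCLN and FGF16, while B3GNT7 passed by r alone (0.84, adjusted p = 0.019). Passing did not order the genes by r, since CA9 and DGAT2 (both r = 0.78) did not pass, while OCLN (0.69) and FGF16 (0.43) did. A gene that did not pass may therefore still follow the oocyte score. ATP8A2 followed the oocyte score with r = 0.99 (permutation p = 1.00e-04, adjusted 8.70e-04) and rho = 0.97 (p = 2.50e-04, adjusted 0.0022), with r = 0.97 without the 2 farthest libraries. For WNT6 r was 0.9 (p = 2.60e-04, adjusted 0.0017) and rho 0.85 (p = 6.80e-04, adjusted 0.0042), with 0.86 without those 2. For EPCAM r was 0.87 (p = 0.0013, adjusted 0.0066) and rho 0.93 (p = 8.70e-04, adjusted 0.0042), with 0.9 without those 2. For OCLN, a member of the granulosa list, r was 0.69 (p = 0.0058, adjusted 0.019) and rho 0.66 (p = 0.013, adjusted 0.043), with 0.68 without those 2. MYCL had r = 0.67 (p = 0.057, adjusted 0.11) and rho = 0.5 (p = 0.14, adjusted 0.25), with 0.75 without those 2, so its 18-fold fall is left undecided by this test. RGS16 had r = 0.11 (p = 0.72, adjusted 0.75) and rho = 0.098 (p = 0.74, adjusted 0.83), with 0.29 without those 2. FST had r = -0.26 (p = 0.52, adjusted 0.62) and rho = -0.31 (p = 0.38, adjusted 0.45), with -0.14 without those 2. Both follicles of a bird enter these 12 values, so they are not fully independent.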
